A study of Rattus norvegicus with 16 samples.

How the data were processed

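The series measured gene expression in the descending thoracic aorta of rats of 4 ages, 3, 6, 15 and 28 months, with 4 arrays per age and 16 arrays in all. Per the labels' protocols, a 1 cm piece of aorta was taken from each rat in random order, kept in RNAlater and homogenised with beads, and biotin-labelled cRNA was made from 5 ug of total RNA. The labels do not say whether the fat around the vessel was removed. The array records name 16 different rats, 1 per array, so the replicates were separate animals.

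The authors deposited 1 table of intensity values, in which each array has 1 signal per probe set on a linear scale. Per the submitters' processing notes the signals were made with MAS5, the Affymetrix method that summarises the perfect match and mismatch probes of a probe set into 1 signal; its version and settings are not given in the sources used here. The deposited signals were already scaled: the mean after trimming 2% of the values at each end lay between 1001.7 and 1002.0 on all 16 arrays, so no further scaling was applied. Median signals lay between 223.5 and 267.7, and the correlation of log2 values between any 2 arrays lay between 0.869 and 0.966. No 2 arrays held the same values. No detection calls were used here, and the number of arrays limits the precision. The deposited array records, text files of type "other" with no measured score, were used for the rat, chip type (RG_U34A), chip lot, fluidics station and hybridisation day of each array and for a note on 10 ug of cRNA. The note is on replicates 2 and 4 at 15 months and 3 and 4 at 28 months and on no other array, and its meaning is not stated.

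The table held 8799 probe sets, of which 59 were controls. By the platform annotation 7006 probe sets had 1 gene symbol, 308 had several and 1426 had none. Of the probe sets with 1 symbol, 6994 had a gene identifier that was found in the RefSeq gene table of the rat, and 0 symbols needed an update. Probe sets with several symbols or none were tested and counted but not named. No genome build is given in the sources used here, so no coordinates are given.

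Values were analysed as log2(signal + 16), so fold changes of dim probe sets are understated. Probe sets with a mean below the 40th percentile and control probe sets were left out, which left 5250 probe sets, with 3153 genes when 1 probe set was kept per gene symbol (that with the highest mean). All 16 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend in the prior), with 1 mean per age and 12 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 5250 probe sets, and the threshold was 0.05. The tests were 5 contrasts between ages, a moderated F test over the 4 ages, and a slope per month of age. All tests were 2-sided. The fat score, described in the report, was compared between ages by an exact permutation test.

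Before the data were examined, 35 gene lists (1223 genes, 782 of them on the array) were written for the tissue and its possible neighbours. Of these, 34 lists had at least 5 genes measured; the list of mesothelial and epithelial markers had fewer and was not tested. Lists were tested with limma's camera with a preset correlation between genes of 0.01, and with an estimated correlation and fry as alternatives, always with 1 probe set per gene. Counts of genes past the threshold in a list are over all probe sets tested and, where said, adjusted over the list alone.

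The genes to be named were also set before the data were examined. For 28 against 3 months these were the 12 largest rises and the 12 largest falls among probe sets past the threshold with 1 symbol and with all 4 arrays of one age above all 4 of the other. For the other comparisons they were the 5 largest in each direction by the same rule. For each list they were up to 4 members past the threshold at 28 against 3 months or, with none, the 2 with the smallest p. To these came 21 genes named whatever their values, of which Cdkn2a and Adipoq had no probe set with that symbol. The largest rises and falls are those of single probe sets, whichever of a gene's probe sets they are. In the lists and among the 21 genes, a gene with several probe sets was represented by the one with the highest mean. Probe sets that disagree are mentioned.

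Replicate numbers 1 to 4 stand for 4 hybridisation runs in the array records, each with 1 array of each age. Runs 1 and 2 shared a day and had chip lots 1 and 2, and runs 3 and 4 shared the other day, day 2, and chip lot 3. The numbers therefore pair the arrays by run, which was decided before the calls were compared. The median correlation of deviations from the age means was 0.171 over the 24 pairs of arrays with the same number (from -0.32 to 0.628, with 13 over 0.1) and -0.034 over pairs with different numbers and ages. The fit without the runs is reported, with the value under the replicate block beside it where it changes a call or moves a count by over 1.5 times. Values within each day rest on 2 arrays per age.

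The tests were tested on simulated data. Noise was drawn for each probe set independently, whereas the measured arrays varied together. The false calls given next therefore do not show the error rate of these data. Besides the 200 changed probe sets, 26 smooth muscle contractile genes were raised by 0.5 at 28 months. On simulated arrays with the measured means and spreads of the 5250 probe sets, 200 of which were changed at 28 months, the comparison of 28 with 3 months called 1.5% of probe sets changed by 0.5 on the log2 scale, 31.3% of those changed by 1 and 87.9% of those changed by 2, with 3 false calls among 83. Alternatives that were tried comprise other pseudocounts, filters and normalizations, other priors, array weights, 1 probe set per gene, the runs, days and chip lots as terms, RNA quality as a covariate, each array left out in turn and other gene list tests. The fat score as a covariate, the omission of 2 arrays with a high beta-actin ratio, a cRNA note as a covariate, single days and the chip lot were chosen after seeing the data.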

Results

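Gene expression was measured in the thoracic aorta of 16 rats, 4 each at 3, 6, 15 and 28 months of age, on 1 Affymetrix rat array per animal. The study addressed how the aorta changes with age, as its title speaks of a progressive disease of the vessel. Of the 8799 probe sets, 5250 were bright enough to be tested. Values are log2(signal + 16) and are given as mean ± SD over 4 arrays, and changes are given with their standard error (SE).

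The aorta pieces differed in their content of fat cell transcripts. A fat score, the mean log2 value of the 34 genes measured from the general adipocyte and brown fat lists, was 12.33 ± 0.52 at 3 months, 12.46 ± 0.68 at 6 months, 11.28 ± 1.60 at 15 months and 10.84 ± 0.57 at 28 months (n = 4 each). At 28 months all 4 arrays lay below all 4 arrays at 3 months (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow, 2-sided). At 15 months replicates 1 and 2 had scores of 12.79 and 12.52, and replicates 3 and 4 had scores of 10 and 9.79 (exact permutation p = 0.343 against 3 months). Ucp1, the uncoupling protein of brown fat, had signals of 60712 and 45054 in the former and 5309 and 4389 in the latter, and between 4128 and 22330 at 28 months. Replicates 1 and 2 were hybridised on day 1 and replicates 3 and 4 on day 2. The first principal component held 47.4% of the variance, and its correlation with the fat score was 0.987 in absolute value.

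**Figure D1:**
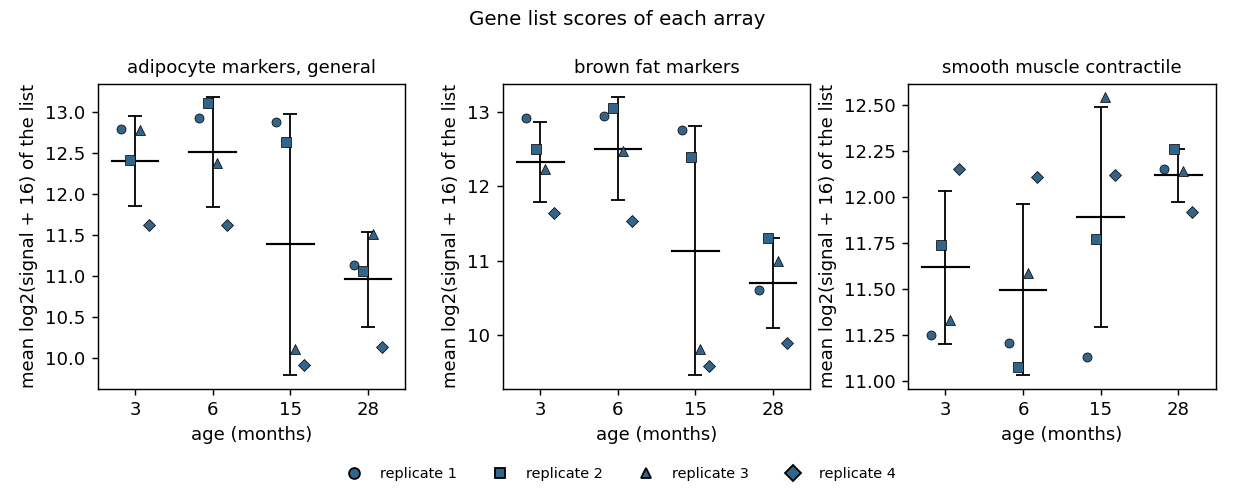
Mean log2(signal + 16) of 3 gene lists (y axes, different ranges) by age in months (x axis); each point is 1 array, its shape gives the replicate number, and the horizontal lines and bars are the mean and SD of 4 arrays. Both fat lists were low on all 4 arrays at 28 months and on replicates 3 and 4 at 15 months, where the fat scores were 10 and 9.79.

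Of the control ratios, that of beta-actin set 2 arrays apart. The ratio of the 3' to the 5' probe sets of beta-actin, which rises as RNA breaks down, was 3.20 on replicate 4 at 15 months and 3.82 on replicate 4 at 28 months, against 1.24 to 1.77 on the other arrays. The same ratio of GAPDH was 1.64 and 2.10 on these arrays, against 1.067 to 1.617 on the others. That of hexokinase was 4.729 and 3.223 on them and reached 5.027 on replicate 3 at 28 months and 4.156 on replicate 4 at 6 months, with 1.005 as the lowest of all arrays. The hexokinase ratio was higher at 28 than at 3 months for each replicate number. It was 3.065, 2.383, 5.027 and 3.223 on replicates 1 to 4 at 28 months, against 2.026, 1.687, 1.683 and 3.124 at 3 months.

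The first question was which transcripts differed between the oldest and the youngest rats. At 28 against 3 months, Uchl1, Vcam1 and Comp were among the genes that rose, and Aspg, Agt and Col1a1 among those that fell. In all, 67 probe sets passed the threshold (limma, adjusted p under 0.05), 55 of them higher and 12 lower, from 50 named genes and 9 probe sets without a single symbol. On all 67, the 4 arrays of one age lay above the 4 of the other, which also held for 931 of the 5250 probe sets tested; chance gives 2.86%. With the replicate block 642 probe sets passed, 343 higher and 299 lower, and they included all 67. Within day 1 the limma count was 699 and within day 2 it was 0 (637 at an unadjusted p under 0.05), with 2 arrays per age. All 55 were higher and all 12 lower on both days, which the separation of the 4 arrays of each age already implies.

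The largest rise of a single probe set was on the dimmest of Uchl1, a ubiquitin hydrolase abundant in neurons (log2 change 2.77, SE 0.45, adjusted p = 0.00876), while its 2 brighter probe sets rose by 1.80 and 1.79. Vcam1, an adhesion molecule that binds leukocytes to endothelium, went from 9.63 ± 0.56 to 12.29 ± 0.21, 6.34-fold higher (log2 change 2.66, SE 0.44, adjusted p = 0.00953), and its other probe set rose by 2.05. Comp, a cartilage matrix protein, rose by 2.58 (SE 0.36, adjusted p = 0.00678). Crabp2, a carrier of retinoic acid, rose by 2.54. Cx3cl1, a membrane-bound chemokine, rose by 2.36 and on another probe set by 1.64 (adjusted p = 0.0123), while another was at 0.17 (adjusted p = 0.664). Spp1, osteopontin, went from 12.31 ± 0.71 to 14.54 ± 0.16 (log2 change 2.23, SE 0.51, adjusted p = 0.0405), and with the fat score as a covariate it was at 1.117 (adjusted p = 0.103). The 12 largest rises also included those of Itgb4, an integrin of epithelial junctions (1.94), Gls2, a glutaminase (1.78), and Chn2, a Rac-regulating protein (1.74). The second probe set of Chn2 was at 1.56 (adjusted p = 0.0865). At 3 months the means of Comp, Crabp2, Itgb4 and the dimmest Uchl1 probe set lay below 7.31, the lowest mean over all arrays that was tested, and no detection calls were used, so the size of these rises is uncertain.

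The largest fall was that of Aspg, an asparaginase, which went from 10.28 ± 0.76 to 6.36 ± 0.93 (log2 change -3.92, SE 0.67, adjusted p = 0.0123). Scgb1c1, a secretoglobin, fell by 2.94 on the log2 scale (adjusted p = 0.0369), and Adcyap1, the neuropeptide PACAP, fell by 2.74 (adjusted p = 0.0143); its other probe set was at -0.42 (adjusted p = 0.299). Agt, angiotensinogen, the precursor of angiotensin II, was 6.00-fold lower (log2 change -2.58, SE 0.40, adjusted p = 0.00876). The 28 month means of Aspg, Scgb1c1, Adcyap1 and Cyth1 lay below 7.31, so the size of these falls is uncertain too. Cyth1, an exchange factor for ARF proteins, fell by 2.20, Pfkp, a phosphofructokinase, fell by 1.28, Slc2a4, the insulin-responsive glucose transporter, fell by 1.14, Slc22a3, an organic cation transporter, fell by 1.14, and Hr, a transcriptional corepressor, fell by 0.94. Second probe sets of Pfkp and Slc22a3 were at -0.96 and -0.89 (adjusted p = 0.121 and 0.162), and that of Slc2a4 at -0.12 (adjusted p = 0.785). Col1a1, a chain of type I collagen, fell by 1.34 and 1.35 on 2 probe sets (adjusted p = 0.0143 and 0.0224). Its brightest probe set was at -0.10 (adjusted p = 0.870) and the remaining one at -1.49 (adjusted p = 0.0623).

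**Figure D2:**
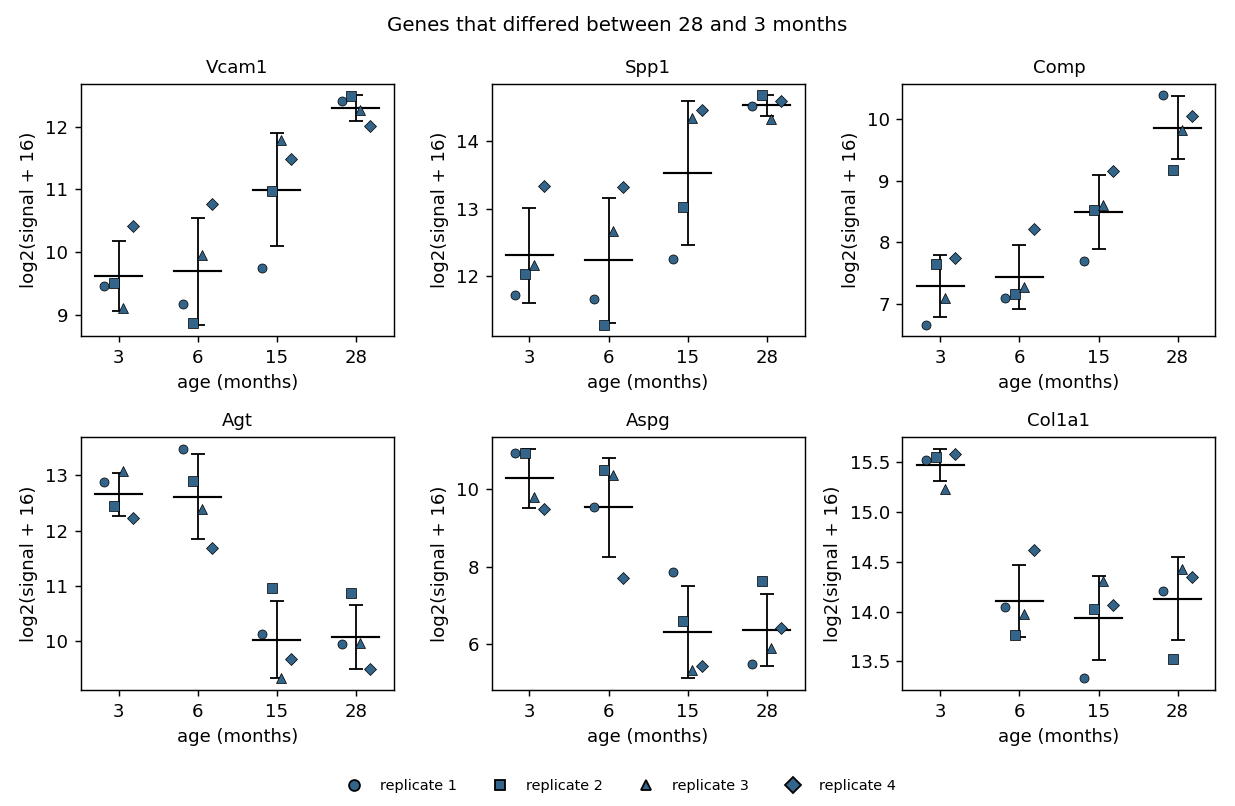
Log2(signal + 16) (y axes, different ranges) of 6 genes by age in months (x axis); each point is 1 array, its shape gives the replicate number, and the horizontal lines and bars are the mean and SD of 4 arrays. Vcam1, Spp1 and Comp were higher on all 4 arrays at 28 months than on any at 3 months, and Agt, Aspg and the Col1a1 probe set shown were lower.

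Limits on the count of 67 came from single arrays. It was 10, 23 and 35 without replicates 1, 2 and 3 at 3 months, 9, 33, 34 and 44 without replicates 1, 2, 3 and 4 at 28 months, 104 without replicate 4 at 6 months and 134 without replicate 1 at 15 months. With the fat score as a covariate, chosen after seeing the data, 40 probe sets passed, 25 of them among the 67, and with the fat score and the replicate block 5 passed; without the 2 arrays with a high beta-actin ratio 43 passed. Among genes named here as risen at 28 months, Crabp2, Spp1, Itgb4, Gls2, Fn1, Bgn, Acvrl1, Tgfb1, Icam1, S100a4, Sdc1 and the second probe sets of Vcam1 and Ccnd1 did not pass with the fat score (adjusted p = 0.0578 to 0.202). Of the falls the same held for Scgb1c1, Adcyap1, Cyth1, Pfkp, Slc2a4 and Slc22a3 (adjusted p = 0.0677 to 0.202). The records of 4 arrays, replicates 2 and 4 at 15 months and 3 and 4 at 28 months, carry a note on the amount of cRNA whose meaning is not stated, and with this note as a covariate, also chosen after seeing the data, 21 passed.

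Genes of fat cells and of fuel oxidation were lower as groups at 28 months. Among 26 general adipocyte genes, 25 were lower and the median change was -1.47 (camera, adjusted p = 1.32e-09; 0.813 with an estimated correlation). Only Slc2a4 passed singly, also when adjusted over the list alone, and with the replicate block 11 passed, all lower. All 9 brown fat genes were lower, with a median of -1.69 (adjusted p = 2.68e-05; adjusted p = 0.813 with an estimated correlation). None passed over all probe sets, 6 fell when adjusted over the list alone and 5 with the replicate block. The SEs of single genes draw on all 4 ages, and the fat score varied most at 15 months. Its SD was 1.60 there, against 0.52 at 3 and 0.57 at 28 months, which widens the SEs of genes that follow it. Fabp3, a fatty acid carrier, was at -2.50 (SE 0.82, adjusted p = 0.122, and 0.0117 with the replicate block). Kcnk3, a potassium channel, was at -0.95 (adjusted p = 0.147, and 0.018 with the block), with its other probe set at -2.53 (adjusted p = 0.162). Ucp1 was at -1.94 (SE 0.75, adjusted p = 0.162, and 0.0365 with the block). Of 25 genes of fatty acid oxidation 24 were lower, with a median of -1.17 (adjusted p = 6.83e-09; adjusted p = 0.813 with an estimated correlation), 0 of them past the threshold singly, and with the replicate block 15 fell and 1 rose. In that list Pdk4, a kinase that restrains pyruvate oxidation, was at -2.87 (SE 0.90, adjusted p = 0.112, and 0.00758 with the replicate block). Of 41 oxidative phosphorylation genes 34 were lower, with a median of -0.65 (adjusted p = 9.93e-09; adjusted p = 0.815 with an estimated correlation), 0 of them past the threshold singly and 12 lower with the replicate block. The ATP synthase chains Atp5f1b and Atp5f1a were at -0.92 and -0.94 (adjusted p = 0.12 and 0.136, and 0.0246 and 0.0287 with the replicate block). All 4 lists had lower medians within both days, at -1.40 and -1.26 for the general adipocyte genes on days 1 and 2. None of the 4 lists passed with the fat score as a covariate. For both fat lists this holds by construction, as the score is the mean of their genes.

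Genes of TGF-beta and BMP signalling, matrix, bone and cartilage and contraction were higher as groups. Of 27 TGF-beta and BMP signalling genes 23 were higher, with a median of 0.63 (camera, adjusted p = 7.45e-04; adjusted p = 0.813 with an estimated correlation). Of these Id3, a target of BMP signals, rose by 1.61 (other probe set at 1.03, adjusted p = 0.0966), Acvrl1, an endothelial receptor of the family, rose by 1.06, and Tgfb1 rose by 1.05 (SE 0.22, adjusted p = 0.0298). These were the 3 past the threshold, against 7 adjusted over the list alone and 8 with the replicate block. Of 25 elastic fibre and other matrix genes 20 were higher, with a median of 0.51 (adjusted p = 3.58e-03; adjusted p = 0.860 with an estimated correlation). Here 4 rose, which were Comp, Postn, periostin (1.71), Fn1, fibronectin (1.58), and Bgn, biglycan (0.92), against 7 higher and 1 lower adjusted over the list alone and 10 higher with the replicate block. Other probe sets of Fn1 were at 1.86, 1.81 and 0.91 and that of Bgn at 0.82, none past the threshold (adjusted p = 0.0869 to 0.398). Elastin (Eln) was at -0.53 (SE 0.18, adjusted p = 0.133). Of 8 osteochondrogenic genes 7 were higher, with a median of 0.33 (adjusted p = 0.0263; adjusted p = 0.813 with an estimated correlation), and Comp and Spp1 passed, against 3 adjusted over the list alone. Comp, Mgp and Fmod are on this list and on the matrix list. Of 26 smooth muscle contractile genes 25 were higher, with a median of 0.48 (adjusted p = 0.0207; adjusted p = 0.896 with an estimated correlation), but 0 passed singly, over all probe sets, over the list alone or with the replicate block. Pln, phospholamban, was at 1.72 and Des, desmin, at 1.34 (adjusted p = 0.129 and 0.162), while Acta2 and Myh11, the actin and myosin of smooth muscle, were at 0.10 and 0.34 (adjusted p = 0.817 and 0.505), with other probe sets at -0.11 and 0.29 for Acta2 and at -0.58 and 0.73 for Myh11. With the fat score as a covariate the medians of these 4 lists were 0.15, 0.05, 0.40 and -0.15 in the same order, with adjusted p = 0.017, 0.710, 0.017 and 0.673. For the 2 lists that passed with it, TGF-beta and BMP signalling and osteochondrogenic genes, adjusted p was 0.549 and 0.464 with an estimated correlation as well, and 0.0823 and 0.088 with the fat score and the replicate block. The smooth muscle list no longer passed with the filter at the 60th percentile (0.0586), without replicates 1 or 3 at 3 months (0.174 and 0.102), without replicate 2 at 28 months (0.104) or on day 2 alone (0.256). The osteochondrogenic list no longer passed with that filter (0.0777), without replicate 1 at 3 months (0.1) or on day 2 alone (0.161). The 5 red blood cell genes were all lower, with a median of -0.54 (adjusted p = 0.0385; adjusted p = 0.815 with an estimated correlation, and 0.0882 with the replicate block). This list also no longer passed with the fat score as a covariate (0.194), with the fat score and the replicate block (0.721), without a filter (0.201), on day 2 alone (0.628) and without replicates 2 or 3 at 3 months, 1 at 15 months or 2 at 28 months (0.0517 to 0.301). The same held with quantile normalization, array weights, the day or chip lot as a term and only the 8 arrays of the 2 ages (0.0591 to 0.075). Of these Slc4a1, the anion exchanger, was at -0.48 and Car2, carbonic anhydrase, at -0.93 (adjusted p = 0.185 and 0.194).

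**Figure D3:**
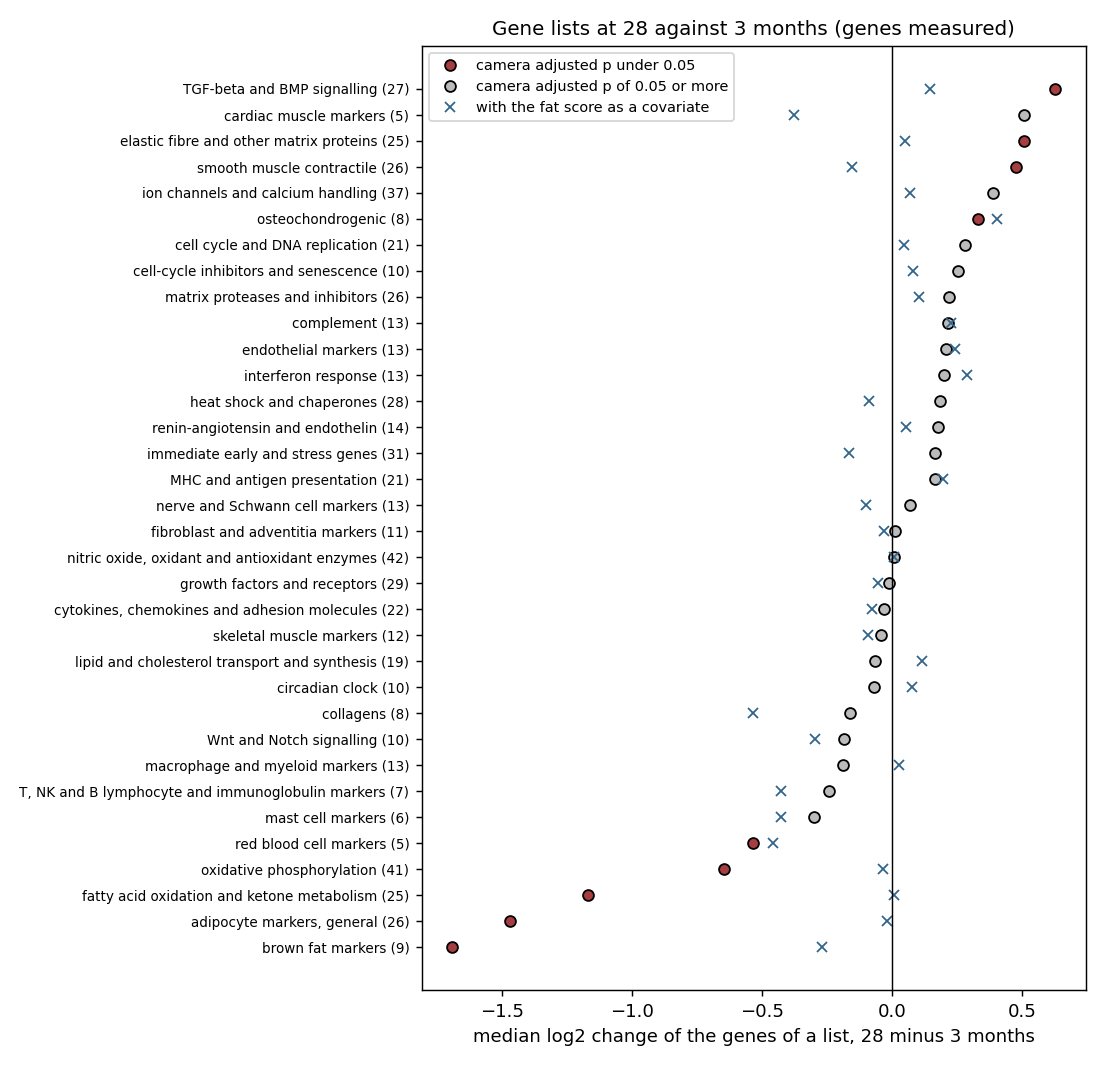
Median log2 change at 28 against 3 months (x axis) of the 34 gene lists tested (y axis, genes measured in brackets); circles are the medians, red where camera's adjusted p was under 0.05, and crosses are the medians with the fat score as a covariate. The medians of the 4 lowest lists lay between -1.69 and -0.65 and between -0.27 and 0.01 with the fat score. The general adipocyte and brown fat lists make up that score, which removes most of their change by construction.

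The other 25 lists did not pass as groups at 28 months, but some held genes that did. Icam1, a leukocyte adhesion molecule, rose by 1.1 (adjusted p = 0.0270; second probe set at 0.64, adjusted p = 0.214), and with Vcam1 it made up the 2 of 13 endothelial markers (list adjusted p = 0.445) and the 2 of 22 cytokines, chemokines and adhesion molecules (0.974) past the threshold. S100a4, a calcium-binding protein of fibroblasts, rose by 1.64 among 11 fibroblast markers (list 0.917), and Uchl1 among 13 nerve markers (0.917). Sdc1, a syndecan, rose by 0.92 among 7 lymphocyte markers (0.664), with a second probe set at 0.27 (adjusted p = 0.660). Gstp1, a glutathione transferase, rose by 0.95 and on its other probe set by 1.01 among 42 nitric oxide and oxidant enzymes (0.974). Ccnd1, cyclin D1, rose by 1.31 among 21 cell cycle genes (0.329, and higher with 0.0303 when all probe sets of a list were used); of its other probe sets 1 rose by 1.25, and the rest were at 1.51 and -0.11 (adjusted p = 0.0533 and 0.83). Agt was the 1 of 14 renin-angiotensin and endothelin genes past the threshold (0.917), beside Ace at 0.73 (adjusted p = 0.0990, and 0.0495 with the replicate block) and Agtr1a at 0.16 (adjusted p = 0.769).

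In the remaining 17 lists no gene passed on its brightest probe set in the fit without the runs, and Col1a1, on the collagen list, fell on 2 others. Under the replicate block Mmp23, Timp2, Lgals3, Clu, C1r, Eif2ak2, RT1-M3-1, Srgn, Pdgfa and Fgfr2 passed (limma, adjusted p = 0.0108 to 0.0426). So did Gja5, Cacna2d1, Fzd1, Fzd2, Cebpb, Dusp6, Hspd1 and Hspe1 (adjusted p = 0.0055 to 0.0353). The other genes named below did not pass with it on their brightest probe set. Among immune lists, of macrophage markers (list adjusted p = 0.313) Lgals3 was at -1.23 and Cd4 at -0.47. Of complement (0.451) Clu was at 1.24 and C1r at 1.1, of interferon response genes (0.528) Eif2ak2 at 0.68 and Irf1 at 0.63, and of antigen presentation genes (0.917) Tap2 at 0.68 and RT1-M3-1 at 0.71. Of mast cell markers (0.664) Srgn was at 0.92 and Cma1 at -0.53. Among wall and growth lists, of collagens (0.503, and lower with 0.00434 when all probe sets of a list were used) Col8a1 was at 0.83 and Col1a2 at -0.55, and Col3a1 was at -0.51 (adjusted p = 0.257). Of matrix proteases and inhibitors (0.664) Mmp23 was at 1.31 and Timp2 at 0.69, and Mmp2 and Timp1 were at 0.26 and 0.64 (adjusted p = 0.535 and 0.165). Of growth factors and receptors (0.974) Pdgfa was at 1.34 and Fgfr2 at 1.78 (other probe sets of Fgfr2 at 0.88 and -0.41), of ion channels (0.0938, and higher with 0.0338 when all probe sets of a list were used) Gja5 was at 2.23 (other probe set at 0.25) and Cacna2d1 at 1.40, and of Wnt and Notch genes (0.974) Fzd1 was at 1.18 and Fzd2 at 0.94. Of senescence genes (0.974) Igfbp3 was at -0.83 and Btg1 at 0.54, and Cdkn1a was at 0.85 (adjusted p = 0.376). Of lipid transport genes (0.451) Insig1 was at -1.13 and Nr1h3 at -0.80. Of stress lists, immediate early genes (0.917) had Cebpb at -1.38 and Dusp6 at 1.00, and chaperones (0.917) had Hspd1 at -1.09 and Hspe1 at -0.70. Of clock genes (0.917) Bhlhe41 was at 0.65 and Nr1d2 at 0.35. Of skeletal (0.806) and cardiac (0.917) muscle markers Myh1 was at -0.77 and Myl7 at -0.68 (other probe set of Myl7 at 0.38). Ccl2, Nos3 and Sod2 were at 0.29, 0.10 and -0.48 (adjusted p = 0.555, 0.890 and 0.225). Median, mean and test of a list differed in sign for the fibroblast, skeletal muscle, clock, cytokine, nitric oxide, growth factor, senescence, Wnt and renin-angiotensin lists, none of which passed.

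The comparison with middle age asked how early such differences appeared. At 15 against 3 months Agt fell by 2.63 (SE 0.40, adjusted p = 0.0250), 6.19-fold, from 12.65 ± 0.39 to 10.02 ± 0.70. Aspg fell by 3.97 (SE 0.67, adjusted p = 0.0285), and Col1a1 fell by 1.53 and 1.59 on the same 2 probe sets as at 28 months (adjusted p = 0.0250 and 0.0286). Bmyc, a relative of the Myc gene, rose by 1.60 (SE 0.26, adjusted p = 0.0250), and at 28 against 3 months by 1.62 (adjusted p = 0.00876), while its other probe sets were at 0.57 and 0.01 at 28 months (adjusted p = 0.292 and 0.991). The means of Aspg at 15 months and of this Bmyc probe set at 3 months also lay below 7.31. These were the 5 probe sets past the threshold, against 10 with the replicate block, 17 with the fat score as a covariate and 2 with the cRNA note. The count was 0, 1, 0 and 0 without replicates 1 to 4 at 3 months and 3, 1, 0 and 0 without replicates 1 to 4 at 15 months.

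As groups at 15 months, general adipocyte (median -1.07, adjusted p = 3.14e-08), brown fat (median -1.20, adjusted p = 6.64e-05), fatty acid oxidation (median -0.72, adjusted p = 4.96e-06) and oxidative phosphorylation genes (median -0.29, adjusted p = 0.0206) were lower than at 3 months by camera. Macrophage markers (median -0.39, adjusted p = 9.66e-04) and collagens (median -0.33, adjusted p = 0.0331) were lower too, and TGF-beta and BMP genes higher (median 0.27, adjusted p = 3.30e-03). With an estimated correlation these had adjusted p = 0.691 to 0.794. With the fat score as a covariate, collagens were lower (adjusted p = 2.99e-06) and oxidative phosphorylation genes were higher (4.76e-06). Macrophage markers (0.135), TGF-beta and BMP genes (0.297), fatty acid oxidation genes (0.275) and both fat lists (0.666) did not pass with it, the fat lists by construction. The lower fat genes at this age rested on replicates 3 and 4, with fat scores of 10 and 9.79. Both were hybridised on day 2 with chip lot 3, so at this age the day cannot be told apart from differences between rats.

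Between 6 and 3 months, 0 probe sets passed in limma, with 151 of 5250 at an unadjusted p under 0.05 and 205 with the replicate block, which also gave 0. Of the 3 lists that passed in camera, 1 was higher, oxidative phosphorylation (median 0.19, adjusted p = 4.77e-05), and collagens (median -0.42, adjusted p = 0.0486) and red blood cell genes (median -0.86, adjusted p = 0.0118) were lower; with an estimated correlation their adjusted p was 0.912, 0.758 and 0.758, and with the fat score as a covariate 9.33e-05, 0.00261 and 0.0146 in the same directions. Col1a1 was at -1.36 (SE 0.25, adjusted p = 0.243) on the brighter of the probe sets that fell later.

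Between neighbouring older ages, 1 probe set passed. Agt fell by 2.59 (SE 0.40, adjusted p = 0.0445), 6.02-fold, from 6 to 15 months; it passed with the replicate block and with the fat score, with the cRNA note limma gave 0 (217 at an unadjusted p under 0.05), and the count was 4 without replicate 4 at 6 months, 1 without replicate 2 at 15 or at 28 months and 0 without any other single array. From 15 to 28 months 0 probe sets passed in limma, with 185 at an unadjusted p under 0.05 and 331 with the replicate block, which also gave 0; the cRNA note as a covariate gave 1. Agt was at 0.05, Vcam1 at 1.30 and Comp at 1.37 in this step (adjusted p = 0.992, 0.967 and 0.967). Within day 1 alone the step from 15 to 28 months gave 515 probe sets in limma, and within day 2 it gave 0 (144 at an unadjusted p under 0.05).

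As groups, general adipocyte (adjusted p = 3.02e-11), brown fat (5.45e-07), fatty acid oxidation (5.63e-10) and oxidative phosphorylation genes (2.32e-09) were lower at 15 than at 6 months by camera, and matrix (0.00453), smooth muscle contractile (0.0106) and TGF-beta and BMP genes (0.0122) were higher. With an estimated correlation their adjusted p was 0.6 to 0.778, and with the fat score as a covariate 0.357 to 0.948. For both fat lists the latter follows by construction. At 28 against 15 months oxidative phosphorylation (adjusted p = 2.66e-10), fatty acid oxidation (2.42e-04) and general adipocyte genes (0.00107) were lower. Matrix proteins (9.06e-04), complement (0.00309), antigen presentation (0.00407), matrix proteases and inhibitors (0.00427), osteochondrogenic (0.0374) and TGF-beta and BMP genes (0.0405) were higher. With an estimated correlation their adjusted p was 0.101 to 0.609. With the fat score as a covariate fatty acid oxidation (0.257), general adipocyte (0.933) and TGF-beta genes (0.0756) did not pass, the adipocyte genes by construction. The others did in the same direction, with adjusted p = 7.76e-08 for oxidative phosphorylation and 3.97e-05 to 0.0182 for the lists that were higher. Brown fat genes had adjusted p = 0.0614 in this step, and 0.0207 with the replicate block.

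Over all 4 ages, 34 probe sets differed by the F test and 698 had a slope with age, 389 of them upward and 309 downward. Comp rose by 0.106 per month (SE 0.0125, adjusted p = 5.64e-04), Vcam1 by 0.112 (adjusted p = 0.0011) and Spp1 by 0.0964 (adjusted p = 0.00509). Fn1, Tgfb1 and Icam1 rose by 0.0699, 0.0469 and 0.046 per month (adjusted p = 0.00387, 0.00389 and 0.00368). Timp1, an inhibitor of matrix proteases, rose by 0.0314 per month (SE 0.00938, adjusted p = 0.0399) and Ace, the angiotensin-converting enzyme, by 0.0325 (SE 0.0085, adjusted p = 0.0274). Agt fell by 0.116 per month (adjusted p = 0.0043) and Ucp1 fell by 0.0869 (SE 0.0268, adjusted p = 0.0437). These slopes do not stand for a steady fall. Agt changed by -0.04 from 3 to 6 months, by -2.59 from 6 to 15 and by 0.05 from 15 to 28. Ucp1 was split at 15 months, with 15.89 and 15.46 on replicates 1 and 2 and 12.38 and 12.1 on replicates 3 and 4. Acta2 and Myh11 had slopes of 0.00996 and 0.0174 (adjusted p = 0.442 and 0.242). With the replicate block 311 probe sets differed by the F test and 1321 had a slope. With the fat score as a covariate 10 differed and 31 had a slope. Of the genes named in this paragraph, Comp and Vcam1 passed with it (adjusted p = 0.0057 and 0.0113), and Spp1, Fn1, Tgfb1, Icam1, Timp1, Ace, Agt and Ucp1 did not (adjusted p = 0.0544 to 0.937).

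The counts over 4 ages also rested on single arrays. The F test gave 34 probe sets in all, and between 2 (without replicate 1 at 28 months) and 89 (without replicate 1 at 15 months) with 1 array left out; only without replicate 4 at 3 months did it stay within 1.5 times. The slope gave 247 and 238 probe sets without replicates 1 and 3 at 3 months, 272, 296 and 330 without replicates 1, 2 and 3 at 6 months, and 196, 235, 439 and 154 without replicates 1 to 4 at 28 months. Without the 2 arrays with a high beta-actin ratio the limma F test gave 0 (572 at an unadjusted p under 0.05) and the slope 172. With the cRNA note as a covariate they gave 0 (439) and 79.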

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

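The tests of fat content, RNA quality and probe sets below were chosen after the results were seen, and what the exchanges of arrays between ages would show was also written after their results were seen.

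In 28 of 508 sets of 4 arrays, 1 array stood apart by a gap that exceeded the 95% critical value of Dixon's test; chance gives about 25.4. Values are log2. At 3 months these were Col1a1 on replicate 3 (15.23), Tap2 on replicate 3 (8.18), Atp5f1b on replicate 4 (14.16), Dusp6 on replicate 2 (9.56), the cytokine list on replicate 1 (9.48) and the TGF-beta list on replicate 4 (9.93). At 6 months they were Comp (8.22), Pdk4 (8.97), Car2 (8.60) and Cacna2d1 (10.31) on replicate 4, Hspe1 on replicate 3 (13.81), and Agtr1a (7.35) and the senescence list (9.20) on replicate 1. At 15 months they were Fgfr2 on replicate 3 (9.64), Ccnd1 on replicate 4 (9.17), Igfbp3 on replicate 1 (9.70), the mast cell list on replicate 2 (8.07) and the log2 beta-actin ratio on replicate 4 (1.68). At 28 months they were Uchl1 (10.91), Pdk4 (4.80) and the log2 GAPDH ratio (1.07) on replicate 4, Tgfb1 (10.71), Ccnd1 (10.05) and the red blood cell list (10.48) on replicate 2, Insig1 (11.71), S100a4 (12.89) and the lipid list (9.82) on replicate 3, and Nr1d2 on replicate 1 (9.16).

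Arrays were also exchanged between the ages. For 28 against 3 months, 1 of 35 splits, the real one, gave as many as 67 probe sets, and the highest other gave 0. By this share chance is unlikely for splits that disregard the runs, but it is not excluded. The real split also set the 4 highest fat scores (11.59 to 12.77, at 3 months) against the 4 lowest (10.02 to 11.32, at 28 months). The exchange therefore does not tell age from the fat score. Only 8 of the 35 part all 4 pairs of a run, too few for a share under 0.05, and with the replicate block the same 8 are all there are; 1 gave as many as the real 642 and the highest other gave 0. For 15 against 3 months 2 of 35 splits gave 5 or more and the highest other gave 470, and for 15 against 6 months 4 of 35 gave 1 or more and the highest other gave 1223, so chance cannot be excluded. The split with 1223 set day 1 against day 2, and with the replicate block 15 against 6 months gave 1. It also set the 4 highest fat scores (12.52 to 13.04) against the rest (9.79 to 12.36), as did the split with 470 (12.52 to 12.79 against 9.79 to 12.39). The next largest, with 1194, crossed the days and set 12.36 to 13.04 against 9.79 to 12.52. Such large counts point to a structure of the samples other than age, which followed the fat score. For 6 against 3 and 28 against 15 months, where limma called 0 (151 and 185 at an unadjusted p under 0.05), all 35 splits gave as many, and the highest others were 0 and 54. Among the 8 splits that part all 4 pairs of a run, the highest other was 0 in each comparison.

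Over all 4 ages, 2 of 100 random exchanges gave as many as 34 probe sets in the F test and 2 of 100 as many as 698 with a slope, the real ones included, with highest others of 842 and 1219. With ages exchanged only within runs, 1 of 100 did in each, and the highest others were 1 and 568. With the replicate block the real 311 and 1321 were again reached by 1 of 100, with highest others of 167 and 1317. By this share chance is unlikely for both. It is not excluded, as the highest other lay close to the real count for the slope.

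General adipocyte and brown fat genes were lower at 28 than at 3 months, and each hybridisation run held 1 array of each age, with a lower fat score at 28 months in all 4 runs. Degraded RNA on the array of old rats with a high beta-actin ratio is argued against, since without it the change was -1.223 with an SE of 0.32 over the arrays at 3 and 28 months, although with the more variable 15 month arrays in the same fit the SE was 0.639. The other 3 arrays at 28 months all lay below the lowest at 3 months, as the separation of all 4 implies. RNA quality on those arrays was not tested by this, and the hexokinase ratio was higher at 28 than at 3 months in all 4 runs. RNA quality in general is therefore not argued against. Less fat tissue in the samples of old rats cannot be told apart from a change of the fat cells, because both kinds of fat gene fell, and the difference of their scores changed by -0.174 with an SE of 0.238. Whether less fat was left on the vessel at dissection cannot be separated from age here, and age itself may account for the fall.

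The second pattern is the 55 probe sets that rose at 28 months. With the fat score as a covariate their median log2 change went from 1.391 (SE 0.273) to 1.002 (SE 0.234) and all 55 were still higher. The SEs in this paragraph are medians of those of single probe sets, not errors of the median change. The 55 were also chosen for their rise on these arrays, which favours a value above 0. Whether less fat tissue was the whole cause is therefore left open. Only 20 of the 55 still passed with the fat score. With the block added 1 did, with a median of 0.984 (SE 0.2825). The changes were smaller with the fat score, and the SE was larger with the block added. Without the 2 arrays with a high beta-actin ratio the median of all 55 was 1.301 (SE 0.298), with 27 past the threshold. The rise thus did not rest on those arrays alone. The choice of the 55 favours a value above 0 here too, and RNA quality on the other arrays was not tested by this. Age stays open as an untested biological explanation, and less fat may have raised single genes, as vessel wall transcripts gain share where fat transcripts lose it.

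The third pattern is the lower Col1a1 at 15 and 28 than at 3 months. On the brighter of the 2 probe sets that passed, the change was already -1.362 (SE 0.246) at 6 months, where it did not pass. This probe set changed by -0.171 from 6 to 15 months and by 0.191 from 15 to 28 months. The amount of fat is argued against, since with the fat score the change at 28 months was -1.678 (SE 0.23, adjusted p = 0.00287), although with the block added it was -1.589 (SE 0.302, adjusted p = 0.068). Without the 2 arrays with a high beta-actin ratio the change was -1.415 (SE 0.278, adjusted p = 0.0385), so the fall did not rest on those arrays alone. RNA quality on the other arrays was not tested by this. A fault of the probe sets that fell cannot be told apart from a change of the gene, because the brightest Col1a1 probe set was at -0.105 (SE 0.314) and at -0.399 (SE 0.335) with the fat score. The remaining Col1a1 probe set, which did not pass before, was at -1.491 (SE 0.373, adjusted p = 0.0623). It was at -2.13 with the fat score (adjusted p = 0.00367). The smaller fall of Col1a2 and Col3a1 was -0.509 (SE 0.263), with an SE of 0.206 with the block, and with the fat score both were lower, at -1.078 and -0.992 (adjusted p = 0.0262 and 0.0304; 0.321 for both with the block added), but they are other genes and do not test the Col1a1 probe sets. Lower collagen I expression with age may be the cause and was not tested apart from this.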

How the results depend on the processing

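The fat score, the omission of both arrays with a high beta-actin ratio, the cRNA note, single days and the chip lot were chosen after seeing the data; all other settings were planned. None of the 35 named probe sets past the threshold at 28 against 3 months changed direction in any setting. Where arrays were dropped, single days used or the pseudocount changed, this was fixed, as all arrays of one age lay above all of the other. Other pseudocounts, the robust prior and both scalings moved no count by over 1.5 times except that from 15 to 6 months. The causes were not tested. Settings with fewer arrays, probe sets or residual degrees of freedom gave lower counts in some cases and higher counts in others. How far dim signals limit the counts was not measured beyond the filters.

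Counts are probe sets in limma for 6 against 3, 15 against 3, 28 against 3, 15 against 6 and 28 against 15 months, the F test and the slope, where they moved by over 1.5 times from 0, 5, 67, 1, 0, 34 and 698. Without a filter 15 against 6 months gave 0, the F test 18 and the slope 354. With the filter at the 60th percentile 15 against 3 months gave 3 and 28 against 15 months 1. Quantile normalization and median centring each gave 0 at 15 against 6 months. Without a trend in the prior it gave 0 and the F test 18. Array weights gave 1 at 6 against 3, 751 at 28 against 3, 0 at 15 against 6 and 1 at 28 against 15 months, 728 in the F test and 1698 slopes. With 1 probe set per gene 15 against 3 months gave 2 and the slope 453. The replicate block gave 10 at 15 against 3 and 642 at 28 against 3 months, 311 in the F test and 1321 slopes, and of the lists at 28 months it changed only the call of red blood cells. The day as a term gave 12, 465, 145 and 1251 for the same 4, and the chip lot 13, 322, 97 and 1225. The GAPDH ratio as a covariate gave 0 at 15 against 6 months and 253 slopes. Only the 8 arrays of the ages compared gave 0 at 15 against 3 (258 at an unadjusted p under 0.05), 535 at 28 against 3 and 0 at 15 against 6 months (214). The log2 of age gave 346 slopes.

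The fat score gave 1, 17 and 40 against 3 months, 1 at 28 against 15 months, 10 in the F test and 31 slopes; with the block it gave 8 at 15 against 3 and 5 at 28 against 3 months, 7 and 4. Without both arrays with a high beta-actin ratio the counts were 0 at 15 against 3 (243), 43 at 28 against 3 and 0 at 15 against 6 months (163), 0 in the F test (572) and 172 slopes. The cRNA note, which 4 arrays at 15 and 28 months carry, gave 2, 21, 0 (217) and 1 from 15 against 3 to 28 against 15 months, 0 in the F test (439) and 79 slopes. Day 1 alone gave 0 at 15 against 3 (375), 699 at 28 against 3, 0 at 15 against 6 (276) and 515 at 28 against 15 months, and 731 in the F test. Day 2 alone gave 0 at 15 against 3 (936), 28 against 3 (637) and 15 against 6 months (718), in the F test (630) and for the slope (859).

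Of 9 gene lists past the threshold at 28 months 0 were left with an estimated correlation, with fry or with the fat score and the block. With all probe sets of a list 12 passed, of which collagens (lower, adjusted p = 0.00434), cell cycle (higher, 0.0303) and ion channel genes (higher, 0.0338) had not passed before. The smooth muscle, osteochondrogenic and red blood cell lists no longer passed in several settings, most of them named in the report, and with fry (0.341, 0.085 and 0.225). With the fat score, camera's direction turned for smooth muscle (adjusted p = 0.673), general adipocyte (0.819), brown fat (0.968), oxidative phosphorylation (0.936) and fatty acid oxidation genes (0.757), and with the block for smooth muscle (0.374) and general adipocyte genes (0.721), the fat lists by construction.

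With each array left out in turn, the counts ranged from 0 to 0 at 6 against 3, 0 to 7 at 15 against 3, 9 to 134 at 28 against 3, 0 to 4 at 15 against 6 and 0 to 1 at 28 against 15 months, from 2 to 89 in the F test, from 154 to 1021 for the slope and from 7 to 10 for the lists.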

Other observations

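The values with the fat score as a covariate were obtained after the data were seen, and the genes named here were chosen after their values were seen. Fat scores at 3 and 28 months did not overlap, so these values rest on the fitted relation to the score. At 28 against 3 months Cox8b and Grifin passed as higher with the covariate, at 0.73 and 1.04 (limma, adjusted p = 0.0416 and 0.0262). Without it they were at -1.65 and -0.88 (adjusted p = 0.308 and 0.524). A rise with the covariate is thus not always a measured rise. At 28 against 3 months, Alb, albumin, was higher on 3 probe sets with this covariate (log2 changes 3.24, 2.60 and 2.08, adjusted p = 7.54e-04, 0.00287 and 7.54e-04), against 0.36, 0.14 and 0.55 without it (adjusted p = 0.878, 0.949 and 0.641). Bmp6, a bone morphogenetic protein, was at 2.67 (SE 0.59, adjusted p = 0.0477), Abcc8, the sulfonylurea receptor, at 2.24 (SE 0.44, adjusted p = 0.029) and Efemp1, a fibulin, at 1.73 (SE 0.35, adjusted p = 0.0319), against 2.11, 0.22 and 1.27 without it (adjusted p = 0.0656, 0.904 and 0.0786). The collagen genes Col1a2 and Col3a1 fell by 1.08 and 0.99 with it (adjusted p = 0.0262 and 0.0304), and so did Sparc, a collagen-binding protein, by 0.82 (adjusted p = 0.0392). Among lists, collagens were lower (camera, adjusted p = 5.95e-04), and endothelial markers, complement and antigen presentation genes (each 0.017) and interferon response genes (0.0177) were higher. With an estimated correlation the lowest adjusted p was 0.340, and with the fat score and the replicate block 0 lists passed.

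Lep, leptin, made by fat cells, was at -0.04 (SE 0.20, adjusted p = 0.922) at 28 against 3 months, while the median of the general adipocyte list it belongs to was -1.47.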
